A study of Danio rerio with 20 samples.

How the data were processed

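The series measured small RNAs in gonads of adult zebrafish (Danio rerio). Piwi-interacting RNAs (piRNAs), the most abundant small RNAs of this tissue, guide Piwi proteins to transcripts of transposable elements, and many begin with U or carry A at position 10. Positions in a small RNA are counted from 1 at its 5′ end. Small RNA libraries came from ovaries of the founder strains Tu and SJD (generation P0), from ovaries of the F1 and F2 generations of the crosses named SJDxTu and TuxSJD, and from Tu and SJD testis. There were 20 libraries in 8 groups. Each of the 6 ovary groups held 3 libraries, of which 2 came from individual females and 1 from pooled RNA of 5 ovaries. Testis had 1 library per strain. The labels do not say which parent of a cross was the mother. Libraries not named as individuals were taken as the pools that the series design describes.

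Per the labels' protocols, total RNA was isolated after lysis with proteinase K and with Trizol LS, and adaptors were ligated to both RNA ends without enzymatic treatment beforehand. Each deposited file held counts, which the authors made by collapsing identical reads to 1 whole-number count per distinct sequence of 18 to 35 nt. Per the submitters' processing notes the genome build was Zv9, but the deposited count files hold no coordinates. The aligner, the read trimmer and their versions are not given in the sources used here. The deposited counts of the TuxSJD F2 pool start at 7 reads per sequence, whereas the 19 other libraries list sequences read once. No genome or transposon annotation was used here, so a feature was a single sequence and its place in the genome is not given.

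Reads with an undetermined base were removed, which were 0.0106% to 2.24% of an ovary library. Reads that shared 10 consecutive bases with the 5′ adaptor of the Illumina small RNA kits were also removed. These were 3.74% to 36.2% of reads in individuals, 0.752% to 4.19% in pools and 0.621% to 0.654% in testis. Reads of 24 to 32 nt were taken as piRNA-sized. Fragments of rRNA, tRNA or miRNAs of these lengths were not removed, so a piRNA-sized sequence need not be a piRNA. Sequences with at least 3 reads in at least 3 libraries were kept as candidates (1028243 sequences), and the filterByExpr function of edgeR left 126409 for the ovary fits. Sequences that differ only in their 3′ end count as different features. The piRNA-sized total was 14786658 to 23027081 reads in pools, 1947935 to 6184884 in individuals and 20546971 to 21402606 in testis. It served as library size. Ovary levels are CPM values of the cpm function of edgeR, scaled to this size times the scaling factor of the fit below. These factors ran from 0.487 (SJD founder pool) to 3.26 (Tu founder individual 1). Testis levels carry no such factor.

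Ovary sequences were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with trimmed mean of M values (TMM) scaling. A single fit over the 18 ovary libraries held the 6 groups and the library kind (pool or individual), left 11 residual degrees of freedom, and gave a biological coefficient of variation of 1.12. Adjusted p-values are from the Benjamini-Hochberg procedure at 0.05, and these tests are two-sided. The contrasts were Tu minus SJD founders, TuxSJD minus SJDxTu in F1, in F2 and as the mean of both, the F2 minus the F1 cross difference, F1 minus founders, and F2 minus F1. Testis was set against the 6 founder ovaries with strain as a block, over 200453 sequences. The strain contrast in testis has 1 library on each side and therefore no p-value. The p-values measure the spread between these samples, since the labels do not say how the females and pools are related.

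A strain index placed each ovary library between the founder strains over the sequences that differed between them. It is the regression of the library's distance from the founder midpoint on the Tu minus SJD difference, on log2 CPM with a prior count of 2. At 0.5 a library lies at the Tu mean and at -0.5 at the SJD mean. Founders were scored with their own library left out. Cross labels were permuted within generation in all 400 arrangements (exact two-sided test). Within 1 generation there are 20 arrangements, and the smallest possible p is 0.1. Shares of read lengths and bases were compared by exact two-sided permutation tests. The number of sequence pairs with a 10-nt overlap of their 5′ ends on opposite strands, the mark of ping-pong amplification, was taken among the 50000 most abundant sequences of each library. It was divided by the mean number at overlaps of 11 to 20 nt. At each overlap only the first 10 bases of 1 sequence had to match the other.

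Known miRNAs were matched by their first 18 bases among reads of 19 to 25 nt (52 sequences, 51 after merging let-7a and let-7c, which share these bases). They fell into 13 lists: gonad, maternal-zygotic, multiciliated and testis, let-7, miR-17-92, broadly expressed, stromal, muscle, blood, liver, neural, epithelial and endothelial. Muscle, blood, liver, neural, epithelial, endothelial and stromal miRNAs stand for other cell types that a dissected gonad could hold. The 44 miRNAs left by filterByExpr were tested with the same model, with the sum of the miRNA counts as library size. Levels given with a test carry the TMM factors of that fit, and the ranking of ovary miRNAs does not. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all of limma 3.58.1, over the 12 lists with a tested member. DESeq2 1.42.0 was the other count model. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

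The groups, contrasts, tests, lists and alternative settings listed below as planned were fixed before the data were examined, as was the rule for the sequences named. It takes the 10 with the largest absolute log2 change in each direction among those with adjusted p under 0.05, at least 50 CPM over the compared groups and no overlap between the libraries of the groups compared. For miRNAs it takes the smallest adjusted p-values and up to 3 members of each list. Names outside the rule are given as chosen after their values were seen. Where testis sequences had 0 reads in the founder ovaries, the fold is a lower bound against 3 reads over these ovaries. Between ovary groups no such fold is given, since ovary levels carry scaling factors and a floor of 3 reads does not. In TuxSJD F2 the pool also lists nothing under 7 reads. Intervals and floors cover counting error only.

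The fit was tested on simulated data made from the means, library sizes and dispersions of 20000 ovary sequences, of which 200 were changed 4-fold, 16-fold or 256-fold. At 256-fold, 37.9% of the changed sequences were called between founders, 27.3% between the F1 crosses, 28.8% between the F2 crosses, 83.3% over both, 90.9% between F1 and founders and 89.4% between F2 and F1. At 16-fold these shares were 0, 0, 0, 13.4%, 22.4% and 25.4%, and at 4-fold 0, 0, 0, 4.48%, 0 and 1.49%, with 0, 0, 0, 4, 6 and 2 false calls. A simulated index of 0.2 and -0.2 was read as 0.194 and -0.205. In simulated miRNA counts with 10 of 44 changed 16-fold between founders, all 10 were called, with 2 calls among the others.

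Alternatives planned beforehand were scaling by relative log expression (RLE) or by total piRNA-sized reads, a fit without the library kind, a replicate block, individuals only, reads of 26 to 28 nt, exchanged F1 and F2 labels of the TuxSJD individuals, founders fitted alone, DESeq2 and each library left out in turn. Added after seeing the data were a light filter, sequences grouped by their first 24 bases, a covariate for the adaptor tag of the individual libraries, counts below 7 set to 0, omission of the 3 libraries with the fewest distinct sequences, and left-out libraries with the filter applied anew. Other splits of the libraries were counted over a random set of 15000 tested sequences. Transposon lists, genomic windows and uniquely placed reads were not analysed here, since they need a genome.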

Results

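Small RNAs were sequenced from ovaries of 2 zebrafish strains, Tu and SJD, from ovaries of the F1 and F2 generations of their reciprocal crosses, and from testis of both strains. The 20 libraries comprised 3 for each of the 6 ovary groups (2 individual females and 1 pool of 5 ovaries) and 1 for each testis group. Founder ovaries gave 6190397 and 5616249 reads in Tu individuals 1 and 2 and 22990032 in the Tu pool, and 3676463, 6345224 and 21347942 in the same order for SJD. SJDxTu ovaries gave 7992769, 8558627 and 25817815 reads in F1 and 8416118, 7015816 and 23678175 in F2. TuxSJD ovaries gave 7615575, 6627826 and 25678679 reads in F1 and 5802029, 8354900 and 16698697 in F2. Testis gave 23702344 reads in Tu and 22987932 in SJD.

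Most reads had the length of piRNAs. Reads of 24 to 32 nt made up 90.0% ± 1.09 (SD, n = 6) of the reads kept in pooled ovaries, 73.6% ± 6.19 (n = 12) in individual ovaries and 90.6% ± 0.544 (n = 2) in testis. The most frequent length was 28 nt, except in SJD founder individual 1, TuxSJD F1 individual 2 and TuxSJD F2 individual 1, where it was 29 nt. Reads of 30 nt or more were 9.70% ± 0.813 in pools and 0.176% ± 0.0648 in individuals, in which no read exceeded 31 nt. Among piRNA-sized reads, 78.4% ± 5.23 in pools, 74.0% ± 4.63 in individuals and 71.7% ± 8.19 in testis began with U. The pair count at a 10-nt 5′ overlap was 5.90 ± 0.405 times the mean of longer overlaps in pools, 4.87 ± 0.437 times in individuals and 4.94 ± 0.0399 times in testis.

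**Figure D1:**
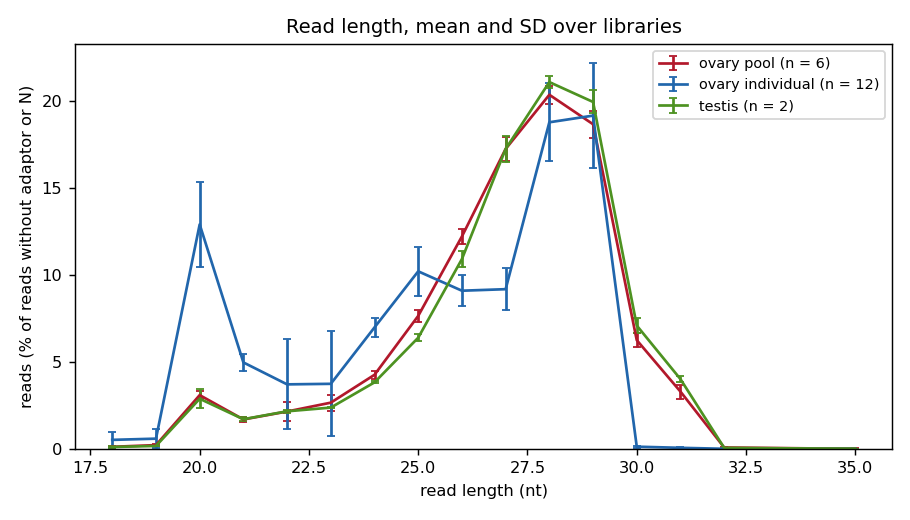
Share of reads (% of reads kept) by read length (nt) as means over 6 pooled ovary, 12 individual ovary and 2 testis libraries, with bars for the SD. The 3 lines peak at 28 or 29 nt, and the individuals alone have few reads from 30 nt on.

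Read composition was compared in 18 exact two-sided permutation tests, which did not keep pools and individuals apart. None passed Benjamini-Hochberg adjustment in this main setting. Alternative settings given below changed this between hybrids and founders. With a replicate block the share of 21 to 23 nt reads passed, and in a narrower length range A at position 10 passed. The 12 hybrid ovaries had 77.3% ± 3.20 first-U reads against 71.8% ± 6.55 in the 6 founder ovaries (exact permutation p = 0.0236, adjusted p = 0.264). Reads of 21 to 23 nt, the size of miRNAs, were 8.70% ± 1.99 of hybrid and 13.9% ± 8.74 of founder reads (exact permutation p = 0.0293, adjusted p = 0.264). By library kind, such reads were 12.4% ± 5.93 in individual ovaries and 6.49% ± 1.12 in pooled ovaries. Tu founders had 17.5% ± 11.7 and SJD founders 10.3% ± 4.03 of such reads (n = 3 each, exact permutation p = 0.4, where 0.1 is the smallest possible). The mean of all founders and that of Tu were raised by Tu founder individual 2 (30.6%), while the SJD founders had 5.73% to 13.3%. Between the crosses, A at position 10 was 43.3% ± 0.896 in TuxSJD and 44.9% ± 1.39 in SJDxTu (n = 6 each, exact permutation p = 0.05, adjusted p = 0.3). The overlap ratio was 5.44 ± 1.06 in Tu and 5.27 ± 0.864 in SJD founders (exact permutation p = 0.9).

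The first comparison asked which small RNAs differ between the ovaries of the founder strains. Tu and SJD ovaries differed in some single piRNA-sized sequences by 3 or more orders of magnitude. TTACACAGTTGCAGTAGACAAAATGACC stood at 427 ± 202 CPM (SD, n = 3) in Tu and 0.216 ± 0.0194 CPM in SJD, a log2 change of 10.85 (SE 1.55, adjusted p = 3.9e-05). TAACTCATTTTGAACTGGACTGCTGGCA stood at 1080 ± 820 CPM in SJD and 1.64 ± 2.04 CPM in Tu (log2 change -9.88, SE 1.51, adjusted p = 0.000115). TAGACGGGAGAGCACATTGACACAGAGA had 2586 reads in Tu and none in SJD. Its Tu mean of 176 ± 235 CPM rests mostly on Tu founder individual 2 (447 CPM, against 37.6 in the Tu pool and 42.8 in individual 1). TGCAGGAGTGCCTGAAGGACAGAAGACC had 1926 reads in SJD and none in Tu. Here the SJD mean of 127 ± 176 CPM rests mostly on SJD founder individual 2 (329 CPM, against 7.87 in the SJD pool and 43.1 in individual 1).

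Of 126409 sequences tested with edgeR, 2925 were higher in Tu and 4236 higher in SJD at an adjusted p under 0.05, and 26947 had an unadjusted p under 0.05. No read was found on the Tu side for 3012 and on the SJD side for 1937 of the 7161. The libraries of the strains did not overlap for 66.9% of these sequences, against 10.98% of all tested and 10% by chance. The rule for named sequences was met by 133, of which 80 were higher in Tu. The 10 largest changes to Tu ran from log2 10.85 to 13.83, and 7 of these sequences, among them TGATGGACATGGCGACGATCAGCATTAAG and ACAGATCGCGACGAAGTCTCAGCGGCTGA, had no read in SJD. The 10 largest to SJD ran from -13.71 to -9.85 and included AACCGTTGAATTCGAGAGCATACTTAAA with 304 ± 439 CPM in SJD against 0.0283 ± 0.0491 in Tu. The 7161 sequences joined into 4301 families by shared 20-base stretches, and 1195 of the 1317 families with at least 2 members (90.7%) pointed in 1 direction. Fitted alone, the founder libraries gave 733 higher and 615 lower, and a fit without the library kind 2 higher and none lower. The median log2 change of all tested sequences was -0.14 with TMM, -0.19 with RLE and 0.04 with total reads, and the share of calls higher in Tu 40.8%, 39.5% (3410 and 5219 higher in SJD) and 49.5% (5698 and 5809). The balance of directions depended on single libraries. With 1 library left out, the calls higher in Tu and in SJD were 845 and 541 (Tu founder individual 2), 1627 and 1258 (Tu founder pool), 2553 and 892 (Tu founder individual 1), 471 and 1952 (SJD founder individual 2), 523 and 1945 (SJD founder pool) and 815 and 3353 (SJD founder individual 1). Their sums were 1386, 2885, 3445, 2423, 2468 and 4168 in this order, and from 812 to 14523 with the filter applied anew.

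In F1 ovaries 11 sequences differed between the reciprocal crosses. The TuxSJD individuals carried the adaptor tag ATCC and the SJDxTu individuals TACA, so cross and tag cannot be told apart among individuals. ATTGATCGAGCGCACAGAATTTACGGCTC stood at 360 ± 179 CPM (SD, n = 3) in TuxSJD and 0.646 ± 0.530 CPM in SJDxTu (log2 change 8.68, SE 1.43, adjusted p = 0.00612). ATTGATCGAGCGCACAGAATTTACGGCT, its form without the last base, stood at 237 ± 141 against 0.332 ± 0.0447 CPM (log2 change 9.37, SE 1.60, adjusted p = 0.00662). TGAAGTAGAAGATGTCAGCTTGACTGCCC was lower in TuxSJD, at 23.3 ± 22.8 against 1699 ± 2203 CPM (log2 change -6.73, SE 1.28, adjusted p = 0.0277). TTAGTTGATTAAAATGTGGTTCGGCGATA stood at 0.141 ± 0.123 against 477 ± 717 CPM (log2 change -13.39, SE 2.38, adjusted p = 0.00993). By edgeR 3 sequences were higher and 8 lower in TuxSJD, 9697 had an unadjusted p under 0.05, and DESeq2 called 596 higher and 752 lower. The higher share of calls was 27.3% with TMM, 51.8% (29 higher and 27 lower) with RLE and 54.5% (225 and 188) with total reads. A fit without the library kind called none (4279 at an unadjusted p under 0.05). Libraries of the crosses did not overlap for 63.6% of the calls, against 13.4% of tested and 10% by chance. The liver miRNA miR-122 stood at 1199 ± 903 CPM of miRNA reads in TuxSJD F1 and 15891 ± 13495 in SJDxTu F1 (log2 change -4.13, adjusted p = 0.123). Leaving out 1 library gave 0 (SJDxTu F1 individual 2), 2 (TuxSJD F1 individual 1), 3 (SJD founder individual 1), 4 (TuxSJD F1 individual 2), 6 (Tu founder individual 1), 19 (SJDxTu F1 individual 1), 41 (TuxSJD F2 pool), 48 (Tu founder individual 2), 56 (TuxSJD F2 individual 1), 62 (TuxSJD F1 pool), 72 (SJDxTu F2 individual 2), 74 (SJDxTu F2 pool), 98 (SJDxTu F2 individual 1), 104 (Tu founder pool), 109 (SJDxTu F1 pool), 132 (SJD founder pool) and 614 (TuxSJD F2 individual 2), and from 0 to 736 with the filter applied anew. Most calls were higher in TuxSJD without TuxSJD F1 individual 1 (2 and 0 lower), TuxSJD F1 individual 2 (3 and 1), the TuxSJD F1 pool (41 and 21), SJD founder individual 1 (2 and 1) or Tu founder individual 1 (4 and 2), and 28 went each way without TuxSJD F2 individual 1. The adjusted p of ATTGATCGAGCGCACAGAATTTACGGCTC with a library left out was 0.05 (SJDxTu F1 individual 1) and 0.153 (SJDxTu F1 individual 2), and that of its shorter form 0.05 (SJDxTu F1 individual 1) and 0.153 (SJDxTu F1 individual 2). For TGAAGTAGAAGATGTCAGCTTGACTGCCC it was 0.141 (TuxSJD F1 individual 2), 0.2 (TuxSJD F1 individual 1) and 0.357 (SJDxTu F1 individual 2), and for TTAGTTGATTAAAATGTGGTTCGGCGATA 0.0876 (TuxSJD F1 individual 1) and 0.775 (SJDxTu F1 individual 2).

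In F2 ovaries 113 sequences differed between the reciprocal crosses. Here the tags of the individuals were reversed (TACA in TuxSJD, ATCC in SJDxTu), so among them cross and tag cannot be told apart either. TCGGAACTCAGAATGATGCATAATGTAAC stood at 1958 ± 2102 CPM (SD, n = 3) in TuxSJD and 6.87 ± 6.09 CPM in SJDxTu (log2 change 8.12, SE 1.38, adjusted p = 0.00989). TGTTGAAAAGTACGGCGTCAAGATACTGG stood at 0.250 ± 0.433 CPM in TuxSJD and 224 ± 214 CPM in SJDxTu (log2 change -10.38, SE 1.84, adjusted p = 0.00989). TACAGGTAGAACAAGTAGATTAGAAAGCT had 3185 reads and TACTTTGGACATTAGAGCAAGGAGGG 2183 reads in SJDxTu, and neither was listed in TuxSJD, whose pool lists nothing under 7 reads, so no least fold is given. TGTAGCAACATGTAGGTCACGTGACATC was higher in TuxSJD, at 380 ± 327 against 3.64 ± 3.34 CPM (log2 change 7.95, adjusted p = 0.0338). By edgeR 25 were higher and 88 lower in TuxSJD, 13487 had an unadjusted p under 0.05, and DESeq2 called 644 and 1312. The higher share was 22.1% with TMM, 33.8% (49 and 96) with RLE and 44.1% (249 and 316) with total reads, and the median log2 change of all tested sequences -0.46, -0.20 and 0.18. Libraries of the crosses did not overlap for 83.2% of the calls, against 12.3% of tested and 10% by chance. With all counts below 7 set to 0 in every library the calls were 17 higher and 22 lower. With the F1 and F2 labels of the TuxSJD individuals exchanged, 1 was higher and 1 lower. None passed in a fit without the library kind (6129 at an unadjusted p under 0.05) or with the adaptor tag as covariate (4626). The sign of TGTAGCAACATGTAGGTCACGTGACATC reversed with exchanged labels (log2 -0.47) and with the tag covariate (log2 -0.32). With 1 library left out, the count was 1 (TuxSJD F2 individual 1; higher), 14 (TuxSJD F2 pool; 11 higher and 3 lower, the reverse balance), 25 (SJD founder individual 1), 26 (SJDxTu F2 individual 2), 65 (TuxSJD F2 individual 2), 67 (SJDxTu F2 individual 1), 176 (TuxSJD F1 individual 1), 184 (SJDxTu F1 individual 1), 189 (SJDxTu F1 individual 2), 234 (Tu founder individual 2), 327 (TuxSJD F1 pool), 373 (SJDxTu F1 pool), 380 (Tu founder individual 1), 408 (SJDxTu F2 pool), 464 (SJD founder pool) and 571 (Tu founder pool), and from 54 to 1671 with the filter applied anew. Left-out libraries that ended a call gave an adjusted p of 0.106 (TuxSJD F2 individual 1) for TGTTGAAAAGTACGGCGTCAAGATACTGG, of 0.0593 (TuxSJD F2 pool) and 0.126 (TuxSJD F2 individual 1) for TACAGGTAGAACAAGTAGATTAGAAAGCT, of 0.0899 (TuxSJD F2 pool), 0.127 (TuxSJD F2 individual 1) and 0.132 (SJDxTu F2 individual 2) for TACTTTGGACATTAGAGCAAGGAGGG, and of 0.0863 (SJDxTu F2 individual 2) and 0.119 (TuxSJD F2 individual 1) for TGTAGCAACATGTAGGTCACGTGACATC.

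Over both generations the crosses differed in 1031 sequences that were higher in TuxSJD and 2014 that were higher in SJDxTu (edgeR, adjusted p under 0.05), and 11992 had an unadjusted p under 0.05. TCGGAACTCAGAATGATGCATAATGTAAC stood at 1294 ± 1582 CPM (SD, n = 6) in TuxSJD and 11.5 ± 7.20 in SJDxTu (log2 change 6.72, SE 0.90, adjusted p = 6.9e-06). ATTGATCGAGCGCACAGAATTTACGGCTC stood at 296 ± 166 against 4.89 ± 7.51 CPM (log2 change 6.69, SE 0.93, adjusted p = 1.3e-05). Among sequences higher in SJDxTu, TGTTGAAAAGTACGGCGTCAAGATACTGG stood at 206 ± 221 against 0.724 ± 1.20 CPM in TuxSJD (log2 change -7.87, SE 1.17, adjusted p = 2.9e-05). AAAAGAACATGTAGGAGAAGGTGTCAG, AAAAGAACATGTAGGAGAAGGTGTCAGT and AAAAGAACATGTAGGAGAAGGTGTCAGTG, which differ in their 3′ ends, had log2 changes of -4.15, -4.20 and -4.50. Libraries of the crosses did not overlap for 35.3% of the calls, against 1.72% of all tested and 0.216% by chance. The named rule was met by 7 higher and 24 lower sequences, the 10 largest of these with log2 changes from -7.87 to -4.15. The higher share was 33.9% with TMM, 37.8% (1222 and 2011) with RLE and 46.8% (1761 and 1998) with total reads, and the median log2 change of all tested sequences -0.27, -0.15 and 0.12. No sequence passed in a fit without the library kind (6798 at an unadjusted p under 0.05). Calls from the individuals alone went the same way in the pools in 176 of 180 cases to TuxSJD (97.8%, against 36.4% of all tested) and 398 of 411 to SJDxTu (96.8%, against 62.7%). Within F1 this was 17 of 25 to SJDxTu (68%, against 52.9%), and within F2 8 of 12 to TuxSJD (66.7%, against 30.6%) and 32 of 32 to SJDxTu (against 66.2%). The count was 2015 (TuxSJD F1 individual 1) and 2019 (TuxSJD F2 pool) with that library left out, and from 2420 to 6097 with the filter applied anew.

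The cross difference itself changed between F1 and F2 for 63 sequences, of which 10 shifted to TuxSJD and 53 to SJDxTu (edgeR, adjusted p under 0.05; 10485 at an unadjusted p under 0.05). DESeq2 gave 522 and 941. The higher share was 15.9% with TMM, 23.2% (13 and 43) with RLE and 30.2% (54 and 125) with total reads, and the median log2 change -0.41, -0.16 and 0.13. Exchanged F1 and F2 labels of the TuxSJD individuals gave no sequence (1772 at an unadjusted p under 0.05), and neither did the adaptor tag covariate (512) or a fit without the library kind (4348). Among the individuals this contrast sets the tag TACA against ATCC, so it cannot be told apart from a tag batch there. Leaving out 1 library gave 2 (SJDxTu F1 individual 2), 3 (TuxSJD F1 individual 2), 5 (Tu founder individual 1), 5 (TuxSJD F2 individual 1), 7 (SJD founder individual 1), 8 (SJDxTu F1 individual 1), 14 (SJDxTu F2 individual 2), 27 (Tu founder pool), 28 (TuxSJD F1 individual 1), 30 (SJD founder individual 2), 247 (TuxSJD F2 pool), 353 (SJDxTu F1 pool), 577 (SJDxTu F2 pool) and 665 (TuxSJD F1 pool), and from 8 to 688 with the filter applied anew. Most shifted to TuxSJD without SJDxTu F1 individual 1 (6 and 2) or TuxSJD F2 individual 1 (4 and 1).

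The next comparison asked whether the sequences that differ between the founder strains also differ between reciprocal hybrids, in the direction of the parent named first. Of the 7161 strain-different sequences, 61.4% (95% exact binomial interval 60.2% to 62.5%) had a cross difference TuxSJD minus SJDxTu of the same sign as the difference Tu minus SJD. Sequences are not independent, so the interval covers counting only. The share was 56.1% for sequences higher in Tu, where 39.4% of all tested went to TuxSJD, and 65.0% for those higher in SJD, where 60.6% of all tested went to SJDxTu. With total reads as scaling it was 68.1% against 54.6% and 54.4% against 45.4%. From the shares of all tested, 51.9% of the 7161 were expected to have the same sign. It was 57.8% in F1 and 61.4% in F2. Of the strain-different sequences, 150 were called higher on both the Tu and the TuxSJD side where 23.9 were expected from independent lists, and 515 were called on the SJD and SJDxTu sides where 67.5 were expected. Opposite calls numbered 110, with 81.2 expected. These expectations take all tested sequences as independent and equally likely to be called, and no test was made on them. TCGGAACTCAGAATGATGCATAATGTAAC was called in opposite directions, with log2 -5.88 between founders and 6.72 between crosses.

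The strain index put these shares on the scale of libraries. Founders had a mean index of 0.294 ± 0.121 (SD, n = 3) in Tu and -0.276 ± 0.141 in SJD. TuxSJD ovaries had -0.00303 ± 0.0460 in F1 and 0.0757 ± 0.00893 in F2, and SJDxTu ovaries -0.0921 ± 0.0263 in F1 and -0.0483 ± 0.0882 in F2 (n = 3 each). Over both generations TuxSJD exceeded SJDxTu by 0.107, in 400 arrangements of the labels the largest difference (exact two-sided permutation p = 0.005, the smallest possible). Within F1 the difference was 0.0891 and within F2 0.124, each with an exact permutation p of 0.1, the smallest possible. Within individuals that share an adaptor tag, and differ in the generation of their label, the difference was 0.151 (TACA tag) and 0.00574 (ATCC tag), and between pools it was 0.163 (2 libraries per cross in each). The exact permutation p was 0.2 without Tu founder individual 1, 0.09 without Tu founder individual 2, 0.07 without the Tu pool, 0.06 without SJD founder individual 1 and 0.11 without the SJD pool. From the individuals alone, over 198 strain-different sequences, the difference was 0.0287 (exact permutation p = 0.944). It was reversed in F1, at -0.0282 (exact permutation p = 0.333), and 0.0857 in F2 (exact permutation p = 0.667).

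**Figure D2:**
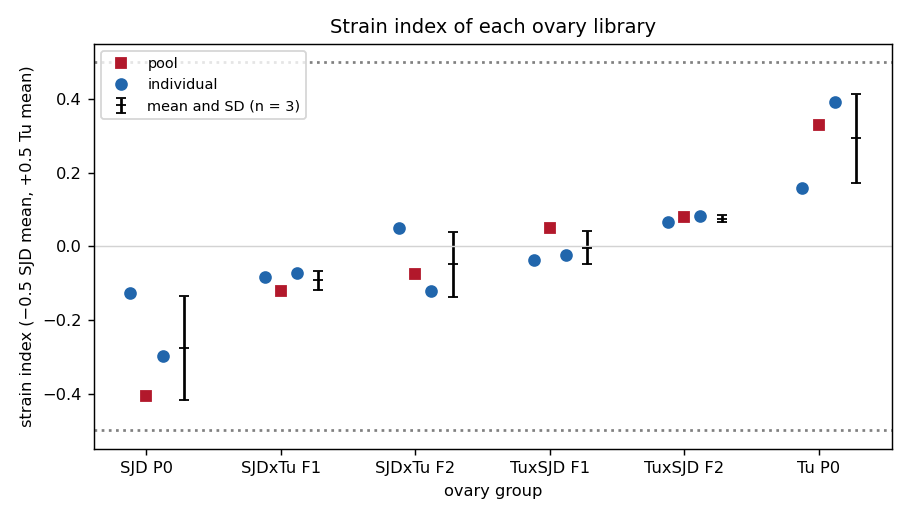
Strain index of each ovary library by group, with pools as squares, individuals as circles, and bars for the mean and SD of 3 libraries. Group means run from -0.276 in SJD founders to 0.294 in Tu founders, and SJDxTu F2 individual 1 (0.0501) lies above the other SJDxTu libraries.

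F1 ovaries were set against the founder ovaries to ask what changed in hybrids of either direction. The contrast takes the mean of the 2 strains on the log scale. A sequence of 1 strain that is intermediate in hybrids can thus count as higher in F1, so the test leans towards higher calls. TAAACTAAGGACAGAGGCTGGCAGTGGA rose from 38.3 ± 46.7 CPM (SD, n = 6) in founders to 205 ± 46.9 CPM in F1 (log2 change 4.79, SE 0.87, adjusted p = 0.00179). Its founder level was 34.0 to 102 CPM in Tu and 0 to 3.34 CPM in SJD. TTTCAATGGATCGCAGCGACGGAGC rose from 88.8 ± 43.7 to 797 ± 628 CPM (log2 change 2.89, SE 0.64, adjusted p = 0.0115). GTGCCAGGGGCGAGGGAAATGTGGCG fell from 192 ± 445 CPM to 0.0131 ± 0.0321 CPM, 1 read in all (log2 change -11.83, SE 1.66, adjusted p = 4.3e-05), and its founder mean rests on Tu founder individual 2 (1101 CPM), as the other founders had 0.216 to 17.3 CPM. TGAGAACTGAATTCCATAGATGGT, a form of miR-146a, fell from 354 ± 723 to 3.94 ± 2.97 CPM (log2 change -6.28, SE 1.10, adjusted p = 0.000958), likewise from 1825 CPM in Tu founder individual 2 and 11.5 to 156 CPM in the other founders. By edgeR 3069 sequences were higher and 547 lower in F1, and 32312 had an unadjusted p under 0.05. The named rule was met by 10 higher sequences (log2 2.82 to 4.79) and 9 lower (log2 -11.83 to -2.49), and libraries did not overlap for 15.6% of calls against 1.69% of tested and 0.216% by chance.

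The 4 founder individuals carried an adaptor tag (ACTA) that no hybrid individual carried. With the tag as covariate no sequence passed between F1 and founders (5585 at an unadjusted p under 0.05), and none without the library kind in the fit (19301). Exchanged F1 and F2 labels of the TuxSJD individuals gave 2281 higher and 548 lower. The individuals alone gave 30440 higher and 2532 lower sequences. Of these, 27510 and 2101 were also tested over all libraries, and in the pools 16174 (58.8%) and 960 (45.7%) of them went the same way, against 57.9% and 41.3% of all tested. The founder individuals Tu 1 and SJD 1 and TuxSJD F2 individual 1 had the fewest distinct piRNA-sized sequences (200126, 275219 and 231824), and without these 3 libraries 187 were higher and 378 lower. The higher share was 84.9% with TMM, 68.1% (1631 and 763) with RLE and 63.8% (4317 and 2454) with total reads. The median log2 change of all tested sequences was 1.21, 0.95 and 0.91 with these scalings, and the log2 changes above are given without subtracting it. Left out singly, 3 founder individuals turned the balance to lower. With 1 library left out, the count was 125 (SJD founder individual 2; 55 higher and 70 lower), 163 (Tu founder individual 2; 100 and 63), 234 (SJD founder individual 1; 94 and 140), 365 (Tu founder individual 1; 128 and 237), 910 (SJDxTu F1 individual 1), 1097 (TuxSJD F1 individual 2), 1225 (TuxSJD F1 individual 1), 2153 (SJDxTu F1 individual 2), 7186 (TuxSJD F2 individual 1), 10920 (TuxSJD F2 individual 2), 17771 (SJD founder pool) and 27862 (Tu founder pool), and from 273 to 35135 with the filter applied anew. Left-out libraries that ended a call gave an adjusted p of 0.0695 (Tu founder individual 2), 0.0757 (Tu founder individual 1) and 0.083 (SJD founder individual 2) for TTTCAATGGATCGCAGCGACGGAGC and of 0.0673 (Tu founder individual 2) for TGAGAACTGAATTCCATAGATGGT.

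F2 ovaries did not differ from F1 ovaries in any of the 126409 sequences by edgeR, where 1844 had an unadjusted p under 0.05. DESeq2 called 13 higher and 7 lower. With edgeR, total reads as scaling gave 12 higher, counts below 7 set to 0 gave 20 higher, and exchanged F1 and F2 labels of the TuxSJD individuals gave 45 higher and 41 lower. The median log2 change was -0.21 with TMM, -0.19 with RLE and 0.07 with total reads. The count without 1 library was 1 (Tu founder pool), 1 (TuxSJD F1 pool), 1 (TuxSJD F2 individual 1), 3 (SJDxTu F2 pool), 4 (SJD founder pool), 4 (SJDxTu F2 individual 1) and 16 (TuxSJD F2 individual 2), and from 1 to 14 with the filter applied anew.

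**Figure D3:**
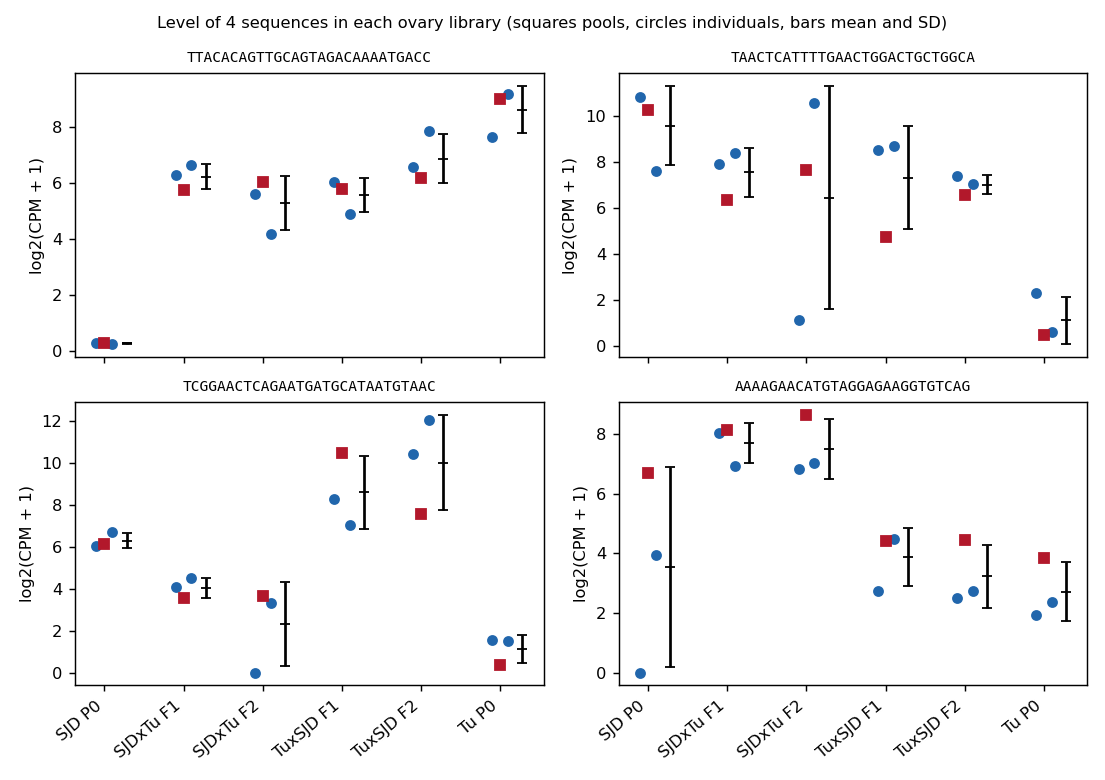
Level (log2 of CPM + 1) of 4 sequences in each ovary library by group, with pools as squares, individuals as circles, and bars for the mean and SD of 3 libraries. TTACACAGTTGCAGTAGACAAAATGACC (10.85) and TAACTCATTTTGAACTGGACTGCTGGCA (-9.88) differed between founders, and TCGGAACTCAGAATGATGCATAATGTAAC (6.72) and AAAAGAACATGTAGGAGAAGGTGTCAG (-4.15) between crosses (log2 changes).

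Testis was compared with founder ovary to ask which small RNAs mark either gonad. TCACAATGCACATGAACAGAAGACAAACA had 120 reads in Tu testis, 1156 in SJD testis and none in the 6 founder ovaries, at least 519-fold more. TAGAAGGATAGGATGTCCTCAAGACAGGC had 366 and 238 testis reads and no ovary read, at least 241-fold more. TTAGTCTTGAGCAGAAACAGAAATAAAGT stood at 199 ± 299 CPM (SD, n = 6) in ovary and had no testis read. These examples were chosen after their values were seen. By edgeR none of 200453 sequences passed (smallest adjusted p 0.151), 18576 had an unadjusted p under 0.05, and RLE scaling gave 22517 higher in testis and DESeq2 27238 higher and 1851 lower. Both of these called 20926 sequences higher. Scaling factors were 0.306 to 0.407 in testis and founder pools and 1.62 to 5.77 in founder individuals. With strain alone as a block, these calls cannot be told apart from library kind. A share of 1.00% (2004 sequences) had reads in testis alone, of which 64.3% began with U and 15.2% had 30 nt or more. A share of 14.7% (29442) had reads in ovary alone, of which 68.3% began with U and 1.60% had 30 nt or more, against 75.5% and 6.80% of all tested. The 2 shares are not alike, as ovary alone asks for no read in 2 testis libraries and testis alone for none in 6 ovary libraries. Reads of 30 nt or more were 0.176% in ovary individuals, 9.70% in pools and 11.2% in testis, so these lengths cannot be told apart from library kind. Set against the 2 founder pools alone, 33389 sequences were higher by over 1 log2 unit and 47254 lower in testis of both strains, and the median log2 change was -0.18 in Tu and -0.26 in SJD.

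The strain difference of the ovary was also read in testis, where 1 library per strain allows no test. Of the sequences higher in Tu ovary, 2416 had testis reads, and 2165 of these (89.6%) were higher in Tu testis, and the list had a median log2 Tu minus SJD of 1.96 with a prior count of 2. Of those higher in SJD ovary, 3225 of 3458 (93.3%) were higher in SJD testis, and the median was -1.60. Across 126409 sequences, which are not independent, Spearman's rho between Tu testis and the founder pools was 0.560 for Tu and 0.276 for SJD, and between SJD testis and the pools 0.508 for SJD and 0.316 for Tu.

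The miRNAs of the ovary were led by miR-21 with 347350 ± 139828 CPM of miRNA reads (SD, n = 18), let-7a and let-7c with 206743 ± 117090, miR-22a with 84049 ± 78406, miR-26a with 73331 ± 69861 and miR-202-5p, a gonad miRNA, with 71038 ± 42495. In testis miR-202-5p stood at 113325 in Tu and 39771 in SJD, and miR-122, the miRNA of hepatocytes, at 6014 in Tu and 119484 in SJD. The miR-430 family of the maternal-zygotic list, which clears maternal transcripts in the embryo, had 2 reads of miR-430c in all ovaries and none of miR-430a and miR-430b. The miRNAs listed here made up 0.224% to 13.9% of reads, the highest in Tu founder individual 2.

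Among the 44 miRNAs tested with edgeR, F1 ovaries differed from founders in 4. miR-146a fell from 240797 ± 441344 to 7885 ± 5336 CPM of miRNA reads (n = 6 each, log2 change -4.89, SE 1.03, adjusted p = 0.00506), with 193821 of its founder reads in Tu founder individual 2, and miR-22a fell from 187304 ± 130436 to 32564 ± 13453 (log2 change -2.33, SE 0.62, adjusted p = 0.0175). let-7d rose from 8221 ± 4351 to 29610 ± 11454 (log2 change 1.88, SE 0.47, adjusted p = 0.0154) with no overlap, and miR-92a of the miR-17-92 list rose from 2728 ± 2358 to 10209 ± 7339 (log2 change 1.83, SE 0.54, adjusted p = 0.0321). With total reads as scaling 25 passed, all lower in F1. With exchanged F1 and F2 labels of the TuxSJD individuals 4 passed, all lower, and let-7d and miR-92a were not among them. With the adaptor tag as covariate none passed (4 at an unadjusted p under 0.05), and the log2 change of miR-146a was 0.0154. Without 1 library the count was 1 (SJD founder individual 2), 1 (Tu founder individual 2) and 1 (TuxSJD F1 individual 1). Left-out libraries that ended a call gave an adjusted p of 0.0581 (Tu founder individual 2), 0.0766 (TuxSJD F1 individual 1) and 0.081 (SJD founder individual 2) for let-7d, of 0.0686 (Tu founder individual 2), 0.081 (SJD founder individual 2), 0.0856 (TuxSJD F1 individual 1) and 0.102 (TuxSJD F1 individual 2) for miR-22a, and of 0.0512 (Tu founder pool), 0.0601 (SJD founder individual 1), 0.0686 (Tu founder individual 2), 0.0692 (SJDxTu F1 individual 2), 0.0872 (SJD founder individual 2), 0.115 (TuxSJD F1 individual 1) and 0.123 (SJDxTu F1 pool) for miR-92a.

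The cross difference of miR-100 changed between F1 and F2 (log2 change 5.33, SE 1.21, adjusted p = 0.0111). That difference was called for 0 (SJD founder individual 2), 0 (SJDxTu F2 individual 1), 0 (SJDxTu F2 individual 2), 0 (TuxSJD F1 individual 1), 0 (TuxSJD F1 individual 2), 2 (SJDxTu F2 pool), 2 (Tu founder individual 1), 3 (TuxSJD F2 individual 2), 4 (SJD founder pool), 5 (TuxSJD F2 individual 1), 6 (TuxSJD F2 pool) and 8 (SJDxTu F1 pool) miRNAs with 1 library left out, and the adjusted p of miR-100 was 0.0554 (SJD founder individual 2), 0.0706 (TuxSJD F1 individual 2), 0.0921 (SJDxTu F2 individual 1), 0.102 (TuxSJD F1 individual 1) and 0.105 (SJDxTu F2 individual 2). In F2 miR-100 stood at 29153 ± 24160 in TuxSJD and 2896 ± 1106 in SJDxTu (log2 change 2.71, adjusted p = 0.176, or 0.0198 without the TuxSJD F2 pool and 0.0366 without the SJDxTu F1 pool). Its reads numbered 1232 to 2175 in the individuals with the TACA tag (SJDxTu F1, TuxSJD F2) and 63 to 171 in those with ATCC. The hybrid pools had 170 to 466, of 142421 to 367487 miRNA reads, against 15731 to 47529 miRNA reads in the hybrid individuals. The change thus lay in the TACA individuals and cannot be told apart from the tag. No miRNA passed between founders (3 at an unadjusted p under 0.05, smallest adjusted p 0.313 for miR-203a), between crosses in F1 (10; DESeq2 4), in F2 (3; DESeq2 2) or over both (2), between F2 and F1 (0), or between testis and ovary (3). miR-34c of the multiciliated and testis list stood at 15.2 ± 17.96 in testis and 812 ± 627 in ovary (log2 change -5.98, adjusted p = 0.232, or 0.00359 without the Tu founder pool, 0.038 without Tu founder individual 1 and 0.0488 without Tu founder individual 2). No library held a read of the whole listed sequence of miR-34c, so its reads match the first 18 bases only. Without 1 library, the F1 count was 2 (TuxSJD F2 individual 1), 3 (SJD founder pool), 5 (TuxSJD F2 individual 2) and 8 (SJDxTu F1 pool), the F2 count 1 (SJDxTu F1 pool) and 1 (TuxSJD F2 pool), and the count between testis and ovary 1 (Tu founder individual 1), 1 (Tu founder individual 2) and 8 (Tu founder pool).

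Of the 13 miRNA lists, the maternal-zygotic one had no tested member. The epithelial list (4 tested) was lower in Tu than in SJD founders by camera (adjusted p = 0.0191, median log2 -1.56), which was adjusted p = 0.478 with an estimated correlation; its member miR-203a stood at 1.98 ± 3.43 in Tu and 121 ± 105 in SJD. The let-7 list (7 tested) was lower in TuxSJD than in SJDxTu F1 (adjusted p = 0.0348, median log2 -1.93), which was adjusted p = 0.630 with an estimated correlation. let-7b stood at 22486 ± 14068 against 92948 ± 59553 (adjusted p = 0.123; 0.00488 without the SJDxTu F1 pool and 0.0291 without TuxSJD F2 individual 2). The broadly expressed list (11 tested) was lower in F1 than in founders (adjusted p = 0.0297, median log2 -1.02), which was adjusted p = 0.270 with an estimated correlation. Between F2 and F1 it was higher (adjusted p = 0.0446, median log2 0.12) and the miR-17-92 list (4 tested) lower (adjusted p = 0.0446, median log2 -0.96), each of which was adjusted p = 0.264 with an estimated correlation. fry gave adjusted p-values of 0.809, 0.101, 0.236, 0.765 and 0.244 for these in turn.

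Adjusted over the list alone, the let-7 list held 4 miRNAs that differed between the F1 crosses, 4 whose cross difference changed between the generations and 1 between F1 and founders. The liver list held miR-122 alone, so its p within the list is unadjusted, and as such it was under 0.05 between the F1 crosses (log2 -4.13), over both generations (log2 -2.07) and for the change of the cross difference between the generations (log2 4.12). Over the 44 tested miRNAs the adjusted p was 0.123, 0.783 and 0.160. The epithelial list so gave 1 between founders, 1 between the F2 crosses and 1 whose cross difference changed. The broadly expressed list gave 1 between the F2 crosses, 1 whose cross difference changed and 3 between F1 and founders, and the miR-17-92 list 1 between F1 and founders. The multiciliated and testis list gave 1 between testis and ovary. The gonad, stromal, muscle, blood, neural and endothelial lists gave 0 adjusted over the list alone in every comparison, and no other list passed camera, the nearest being miR-17-92 over both generations (adjusted p = 0.0871).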

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

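The tests of the libraries with few distinct sequences, of exchanged generation labels and of other splits were chosen after the result was seen, and those of the adaptor tags and of single libraries before.

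The cross difference of 63 sequences changed between F1 and F2 by the test of that change itself, as did that of miR-100 (log2 5.33). miR-100 stood at 2897 ± 1718 in TuxSJD and 23896 ± 19523 in SJDxTu in F1, and at 29153 ± 24160 and 2896 ± 1106 in F2 (CPM of miRNA reads, n = 3 each). Its high values lay in the individuals with the TACA tag and not in the pools, so this change cannot be told apart from the tag. With the F1 and F2 labels of the TuxSJD individuals exchanged, 0 sequences passed and the log2 value of miR-100 was -0.29. Reads that hold 5′ adaptor sequence lie outside the comparisons, and they reached 36.2% of the reads in SJDxTu F1 individual 2.

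The adaptor reads of the individual libraries carry a 4-base tag, which was ACTA in the founders, TACA in SJDxTu F1 and ATCC in SJDxTu F2. In TuxSJD the individuals labelled F1 carried ATCC and those labelled F2 carried TACA, the reverse of SJDxTu, and the names of their deposited files also give the other generation. Within F1 and within F2 the individuals of the crosses thus differ in tag. The F2 minus F1 cross difference among them is TACA against ATCC. For exchanged generation labels of TuxSJD individuals, each of the 4 TuxSJD individuals would lie closer to the pool of the other generation, and 3 of 4 did, relative to their mean. The rank correlations with the pools ran from -0.0229 to 0.0488 across 100614 sequences, which are not independent, and differed by at most 0.0627. Correlations this small show no likeness to either pool, so this check cannot bear on the labels. From the tags and file names, an exchange of the labels may have occurred and cannot be told apart from a different order of preparation. Such an exchange would alter each comparison that uses F1 or F2 apart, that of F1 with founders included.

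F1 ovaries differed from the log-scale mean of the founder strains in 3616 sequences. In a random set of 15000 sequences the real split gave 429 calls and the highest of the other 99 splits 42, so 1 of 100 splits gave as many. Chance is thus unlikely but not excluded, since only 100 splits were drawn and the others do not keep strains and library kinds balanced. The adaptor tag differs between founder and hybrid individuals. Sequences called from the individuals and also tested over all libraries exceeded the share of all sequences in the pools, where the most frequent tag was at most 0.00661% of reads, by 0.898 percentage points in the rising and 4.38 in the falling direction, below the 5 points set for a difference apart from the tag. A tag batch therefore cannot be told apart from the cross for these calls. Without the 3 libraries of fewest distinct sequences, of which 2 are founders, 565 calls were left, so these libraries may account for part of the count, and a biological change in hybrids stays open and was not tested apart from them.

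TuxSJD ovaries lay closer to Tu in the strain index than SJDxTu ovaries, by 0.107. The difference was 0.0614 to 0.144 with any 1 library left out, but its test depended on single founder libraries, as the exact permutation p was 0.2 without Tu founder individual 1, 0.11 without the SJD pool, 0.09 without Tu founder individual 2, 0.07 without the Tu pool and 0.06 without SJD founder individual 1. Within the ATCC tag the difference was 0.00574, with an SD within crosses of 0.0854, and within the TACA tag 0.151 (SD 0.0101), so a tag batch could not be excluded from 2 individuals per cross and tag. Between pools the difference was 0.163. From the individuals alone, as given above, it was smaller than with any 1 library left out and was reversed in F1. Exchanging the generation labels left the difference at 0.107, as equal group sizes make it do, and tests nothing. An effect of the direction of the cross may exist, and the parents' strains stay among the open explanations.

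Over both generations, the split of the 12 hybrid libraries by cross gave 362 calls among 15000 sequences, the highest other 136, and 1 of 100 splits gave as many. Chance is unlikely there but is not excluded by 100 splits, of which the others do not keep library kinds balanced. Between F2 and F1 the real split gave 0 and the highest other 87, and since all 100 splits reach 0 by construction, they say nothing about chance there. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real split gave 852 calls between founders, 13 between the F1 crosses and 43 between the F2 crosses, the highest other 0 in each.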

How the results depend on the processing

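Chosen after seeing the data were the light filter, the first 24 bases, the adaptor tag covariate, counts below 7 set to 0, the omission of the 3 libraries with the fewest distinct sequences, and left-out libraries with the filter applied anew. The counts of sequences depend on the setting throughout, and unless its construction shows it, the cause was not tested. Planned but not run were a fit of the piRNA-sized sequences with no filter, which was run for miRNAs only, and uniquely placed reads and genomic windows. Requiring a founder log2 change of at least 1 moved no index value, since all called sequences met it. Depth limits the individuals, which have 1947935 to 6184884 piRNA-sized reads. Values below are given for founders, F1 crosses, F2 crosses, both generations, F2 minus F1 cross difference, F1 against founders and F2 against F1 in this order, where not named.

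The light filter gave 1995, 32, 171, 11830, 131, 2092 and 3, and a direction share of 62.8%. Total reads gave 11507, 413, 565, 3759, 179, 6771 and 12, and DESeq2 13683, 1348, 1956, 3357, 1463, 12485 and 20. RLE gave 56 between F1 crosses and 2394 for F1 against founders. The fit without the library kind gave 2 between founders, 0 in the 5 next comparisons and a direction share of 100%. Individuals alone gave 198, 29, 44, 615, 638, 32972 and 1, an index difference of 0.0287, of -0.0282 in F1, and direction shares of 54.5% and, in F1, 47.5%. Reads of 26 to 28 nt gave 3974, 19, 89, 1670, 33 and 1564. Founders alone gave 1348. Counts below 7 set to 0 gave 2326 between founders, 67 and 39 in F1 and F2 crosses, and 20 for F2 against F1. The first 24 bases gave 216 and 823 between F1 and F2 crosses and 131 for their difference. Exchanged labels gave 42 and 2 between F1 and F2 crosses, 0 for their difference and 86 for F2 against F1. Without the 3 libraries of fewest distinct sequences the counts were 755, 17, 5529, 0 and 565 from F1 crosses to F1 against founders. The adaptor tag covariate gave 0 between F2 crosses, 0 for the difference, 0 for F1 against founders and 2 for F2 against F1. Testis against ovary gave 22517 with RLE and 29089 with DESeq2.

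With 1 library left out, under both filters, the counts ran from 812 to 14523, 0 to 736, 1 to 1671, 2015 to 6097, 2 to 688, 125 to 35135 and 0 to 16. The index difference ran from 0.0614 to 0.144 and the direction share from 57.0% to 67.5%. miRNA counts ran from 0 to 8 between F1 crosses, 0 to 1 between F2 crosses, 0 to 8 for the difference, 1 to 6 for F1 against founders and 0 to 8 for testis.

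A replicate block gave 55 between F1 crosses, 234 between F2 crosses, 165 for their difference and 2 for F2 against F1. With the replicate block the 21 to 23 nt share differed by -5.22 points between hybrids and founders (adjusted p = 0.0145), and the broadly expressed and miR-17-92 lists had an adjusted p of 0.0582 for F2 against F1. Replicate numbers do not pair the individuals, since those numbered 1 had correlations from -0.0999 to 0.164 across groups. The pools did move together, as their deviations from the group means had correlations from 0.440 to 0.858.

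For miRNAs, total reads gave 2 between F1 crosses, 6 for the difference, 25 for F1 against founders and 3 for testis. DESeq2 gave 4 between F1 and 2 between F2 crosses, 3 for the difference and 7 for F1 against founders. No filter gave 2 for F1 against founders. Exchanged labels gave 1 between F1 crosses, 0 for the difference, 4 for F1 against founders (0 higher, which ends the calls of let-7d and miR-92a) and 1 for F2 against F1. The tag covariate gave 0 for the difference and 0 for F1 against founders. List values with an estimated correlation were 0.478 (epithelial, founders), 0.630 (let-7, F1 crosses), 0.270 (broad, F1 against founders) and 0.264 (broad and miR-17-92, F2 against F1), and by fry 0.809, 0.101, 0.236, 0.765 and 0.244.

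Signs reversed for TGTAGCAACATGTAGGTCACGTGACATC in F2 (-0.47 with exchanged labels, -0.32 with the tag covariate), TCAACGATGATTAGCAGATAACAGAGGCA in F2 (0.15 with exchanged labels), miR-100 with exchanged labels (-0.29, F2 minus F1), let-7d with exchanged labels (0.33, F2 against F1) and miR-146a with the tag covariate (0.0154, F1 against founders). Exchanged labels gave -0.0431 for miR-100, miRNAs, reciprocal cross difference in F2 ovary, likewise reversed. No other sequence or miRNA that was followed across the settings reversed.

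In distinct sequences, the founder difference reversed for reads of 26 to 28 nt (0.586 points) and for A at position 10 without first U (0.160 points; crosses 0.520). In reads of 26 to 28 nt, A at position 10 reversed between founders (-0.713), was -3.29 between hybrids and founders (adjusted p = 0.0187), and without first U reversed there (-0.217). With 1 library left out, founder differences ran from -6.87 to 3.90 points for 26 to 28 nt, -3.73 to 6.17 for first U, -1.79 to 2.19 for A at position 10 and -0.438 to 0.524 for the overlap ratio. Hybrid against founder differences ran from 3.44 to 7.41 for first U, -2.90 to -1.31 for A at position 10, -0.374 to 2.03 for it without first U and -0.428 to 0.0444 for the overlap ratio. Cross differences ran from -0.958 to 3.16 for 26 to 28 nt, -1.24 to 2.10 for first U and -0.415 to 0.0416 for the overlap ratio.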

Other observations

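The tests of this part were set before their results were seen, except that the pairs and tokens shown were chosen after their values were seen.

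Among strain-different sequences, 363 pairs differed at 1 base. TCGGAACTCAGAATGATGTATAATGTAAC was higher in Tu (log2 8.52) and TCGGAACTCAGAATGATGCATAATGTAAC in SJD (log2 -5.88), a T19C pair (positions count from 1 at the 5′ end), and both were higher in TuxSJD than in SJDxTu (log2 5.91 and 6.72). TCCGGTCACTGCACTGCTCAAGAAGATGG was higher in Tu (log2 8.43) and TCCGGTCGCTGCACTGCTCAAGAAGATGG in SJD (log2 -4.91), an A8G pair. A hypothesis was that such pairs are alleles of 1 piRNA, which would make opposite directions frequent. Opposite directions were found in 151 pairs (41.6%) against 48.3% under 10000 shuffles (one-sided permutation p = 0.994), so they were not more frequent. The shuffles treat sequences as independent, whereas 1195 of 1317 families of related sequences pointed in 1 direction. The test therefore cannot decide whether some of the pairs are alleles.

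A further hypothesis was that ping-pong partners of a locus may change together between the strains. Among pairs of strain-different sequences with a 10-nt 5′ overlap, 65 of 110 (59.1%) pointed in the same direction, against 16 of 31 (51.6%) at overlaps of 11 to 20 nt. Here the whole overlap had to match, unlike in the overlap ratio of the libraries. The difference of 7.48 percentage points between these shares exceeded the 5 points set beforehand. Its standard error was 10.1 points (two-sided Fisher's exact test p = 0.539), so the pairs were too few to decide.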
